A study of Apis mellifera with 22 samples.

How the data were processed

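Gene expression was measured by spotted one-colour arrays on whole-body RNA of honey bees. Per the labels, each sample pooled 50 bees of 1 hive on 1 day, and 0.2 µg of RNA was labelled with Cy3 by a low-input amplification kit. Samples were grouped by crop and day as the labels give them. The 16 arrays of hives 1 to 4 made 8 groups of 2, and the standard and double-sided hives had 1 array per day. The labels name separate hives, so the arrays of a group come from separate colonies, but each is a single pool and its technical spread was not measured apart from that of the colonies.

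Per the file headers, the deposited array files hold spot intensity on a linear scale (signal mean and background median of each of 28800 spots), not normalized. The authors' value table holds intensity too. Its ranks within each array equalled those of the mean signal of the averaged spots (Spearman 1) and its median was 266 on each of the 16 arrays and 199 on each of the other 6, so these were scaled as separate sets, on a linear scale and without background subtraction. Per the submitters' processing notes RMA and Partek were used, with versions not given in the sources used here. Whether further steps preceded the scaling stays unknown. Every sample column of that table was used. Its 2 rows with ranks far from those of the mean signal on every array could not be placed and were left out, also from that correlation.

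Probes were named from the array files, and gene identifiers were matched to the reference gene table of assembly Amel_HAv3.1, used for names alone. Of 12778 bee and pathogen probes, 8230 had a gene identifier, 8070 of them as a locus number, 10 by accession and 150 by symbol. A current symbol was found for 7257, and 4654 had a usable name. The array also carried 25 negative control probes, 802 buffer spots, 386 blank spots and 30 pathogen probes. The 109 antisense probes were left out of the tests. Names are those of the array's design and can be old.

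Background was corrected with normexp (offset 50) on all spots, arrays were quantile normalized in 2 sets (hives 1 to 4, and the other 6 arrays), and spots of a probe were averaged on the log2 scale. The design had been written for another scanner format with 75th percentile scaling. The files proved to be spot quantifications, so normexp with quantile scaling became the main setting and 75th percentile scaling an alternative. A probe was above background on an array when its mean signal exceeded the 90th percentile of the negative controls. A gene was represented by its brightest probe, and was tested when above background on every array of at least 1 of the 8 groups, which left 9959 of 12150 genes. Where a gene was not above background on any array of the dimmer group, the text gives a bound ("at least N-fold"), the brighter mean against the higher of the probe's own signal and the lowest signal above background on each array.

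Tests used limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, on all 16 arrays with 1 coefficient per crop and day, so that groups of 2 share 1 estimate of the spread. Contrasts compared days 14, 42 and 70 with day 0 over both crops and in each crop, the crops at day 0, and the change between crops (an F-test). All tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Gene lists were tested with camera (preset correlation 0.01, and again with an estimated one) in limma, adjusted over 27 lists of at least 3 genes. All p-values of lists in the text are camera's. The lists were text patterns on gene names: 5 on the study's theme (antimicrobial peptides and lysozymes, immune recognition and melanization, immune signalling, antioxidant enzymes, glutathione S-transferases) and others for detoxification, stress, metabolism, housekeeping and tissue or cell markers, of which 3 passed at a pooled day (ribosomal proteins, proteasome, carboxylesterases and UDP-glucuronosyltransferases). The other 19, markers of gland, fat body, venom gland, antenna, muscle, eye, nerve, cuticle, gut, ovary and dividing cells among them, passed at no pooled day. Patterns match names and not functions: immune recognition holds the ubiquitin protease USP14 (LOC411572) and immune signalling the nuclear receptor LOC409246. Apidermin 1 (Apd-1) was in no cuticle list. Probes without a gene identifier counted as genes of their own, so related entries such as the apidaecins could each count as a list member.

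The lists, tests, groups, most alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 8 largest rises and falls among named genes past the threshold with the same sign in all 4 hives (per crop, the 4 largest of each), up to 4 members by p of each theme list and up to 3 of other lists past the threshold, the 6 largest of each sign by hive type, and the pathogen probes. Where none passed, as many by smallest p were taken. Of the pathogen probes other than Deformed wing virus, none passed at a pooled day.

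Hive numbers pair the arrays, since the labels follow the same colony over time. Deviations of same-numbered arrays from their group means correlated at r = -0.05 to 0.18 across genes, and the consensus correlation within hive was 0.015. A fit with hive as a block was planned as an alternative. The image names give 3 series for hives 1 to 4, and each slide held 1 array. Random sets were 10000 per list or gene group, matched on mean expression in 20 bins.

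The code was tested on simulated data with the real arrays' spread and 200 of 9959 genes changed. For the pooled contrast of day 42, 61.5% of 2-fold and 95.5% of 4-fold changes were recovered, with 6 and 10 false calls. In the strawberry contrast of day 42 the shares were 13.5% and 87.5%, and in that of eggplant 19.0% and 85.5%. With no change, 0 genes were called. Simulated groups with no change against shared day 0 arrays were drawn 20 times, and intervals used 2000 bootstrap draws. Alternatives covered the block, background correction, scaling, the authors' value table, the filter on dim probes, the trend, the choice of probe, the arrays in the fit, additive terms, single hives left out and the added hives. Other versions were statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.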

Results

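The series followed honey bee (Apis mellifera) colonies that were put into greenhouses where strawberry or eggplant was grown, and by its title it asked about immune and oxidative stress transcripts. Each array measured whole-body RNA of 50 pooled bees of 1 hive on 1 day. Hives 1 and 2 stood with strawberry and hives 3 and 4 with eggplant. Each was sampled before it was moved (day 0) and at days 14, 42 and 70, which gave 16 arrays in 8 groups of 2. A further 6 arrays came from a standard hive and a hive with a double-sided entrance, both with strawberry, at days 0, 42 and 70. The number of arrays limits the precision. The median spot signal was 206.8 to 339.6 on the arrays of days 0, 14 and 42 and 143.2 to 202.5 on the 4 arrays of day 70, and 55.1% to 83.4% of probes lay above background. Paired arrays of a group correlated at r = 0.77 to 0.90 across genes, which are not independent replicates. Of 12150 genes on the array, 9959 were tested, 3716 of them with a name. All colonies stayed in greenhouses, so time since the move cannot be told apart from season or the age of the bees. The array images fell into 3 series, which are treated here as batches. Series 1 held strawberry days 0 and 42, series 2 held strawberry day 14 and eggplant days 0, 14 and 42, and series 3 held every day 70 array.

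At day 14, antimicrobial peptides, which kill microbes in the haemolymph, were lower as a group than before the move. Of 7 members, 6 lay below day 0, and the median log2 change was -2.26 (-0.87 with strawberry, -2.47 with eggplant; camera adjusted p = 1.81e-05). With an estimated correlation the adjusted p was 0.0640 and the call was lost. The largest decreases among them were those of apidaecins, at -2.71 ± 0.52 for Apid1 (SE, n = 4 hives against 4; 10.03 ± 1.12 against 12.73 ± 0.92, SD) and -2.36 ± 0.44 for GB13473-RA, with GB17782-RA at -2.26 ± 0.50 and hymenoptaecin (LOC406142) at -2.27 ± 0.57. The list median was the value of GB17782-RA. GB13473-RA and GB17782-RA had no gene identifier and were counted as members apart from Apid1. Member counts and p-values of this list, here and below, can therefore count closely related transcripts more than once. Antioxidant enzymes were lower as a group, with 19 of 25 members lower and a median of -0.33 (adjusted p = 0.000634, or 0.465 with an estimated correlation, which lost the call). So were glutathione S-transferases, which couple glutathione to toxic or oxidised compounds, with 5 of 6 lower and a median of -0.84 (-1.41 with strawberry, -0.14 with eggplant; adjusted p = 0.00265, or 0.428 and no call with an estimated correlation). Among their members the iron-storing ferritin LOC551651 was at -1.57 ± 0.31, the hydrogen peroxide-degrading catalase (Cat) at -1.41 ± 0.31, the glutathione S-transferase LOC552283 at -1.24 ± 0.25 and GstS1 at -1.10. Carboxylesterases and UDP-glucuronosyltransferases, which modify foreign compounds, were higher as a group (4 of 4 members, median 0.46, adjusted p = 0.0140, or 0.230 and no call with an estimated correlation), led by Est-6 at 0.70 (at least 1.23-fold) and UGT35b (LOC725997) at 0.60. Without hive 1 or without hive 4, 0 lists were higher, so that call was lost there too.

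Ribosomal proteins (21 of 23 lower, median -0.37, with -0.72 in strawberry and -0.07 in eggplant, adjusted p = 0.00149) and proteasome subunits (19 of 27 lower, median -0.39, adjusted p = 0.000145) were also lower as groups at day 14, and both calls were lost with an estimated correlation (0.493 and 0.428). Among their members, RpL15 (LOC413137) was at -0.74 and the proteasome subunit LOC409831 at -0.85. Immune recognition and melanization genes (median -0.09, adjusted p = 0.601) did not pass. The largest change by p among the immune signalling genes was that of hopscotch (LOC726002), the Janus kinase, at 0.46 (limma adjusted p = 0.313). Its 4 spots disagreed in direction, from -0.15 to 0.98. The median of the signalling list was 0.03 while its mean was -0.000665 (adjusted p = 0.9987). Counts adjusted over the list alone were 5 lower antimicrobial peptides, 2 lower antioxidant enzymes, 4 lower glutathione S-transferases, 2 lower proteasome subunits, 2 higher carboxylesterases or transferases and 0 ribosomal proteins.

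No gene by itself passed limma's test at day 14, where the smallest adjusted p was 0.0683 and 1214 genes had an unadjusted p under 0.05, against 498 by chance. Among those nearest to passing were the metal transporter Malvolio (LOC727033) at -1.54 ± 0.27, the basement membrane protein Nidogen (LOC408797) at -1.63 ± 0.33, a tubulin (LOC408388) at -1.46, the gap junction protein Innexin-7 (LOC552285) at -0.98, the clock gene Per at 1.04 ± 0.21 (at least 1.67-fold) and the cuticle protein apidermin 1 (Apd-1) at 3.02 ± 0.66. A fit with hive as a block passed 27 genes, 5 higher and 22 lower, among them Per, Malvolio, Apid1, GB13473-RA and ferritin LOC551651, each at an adjusted p of 0.0477, and Nidogen at 0.0452. Other fits gave 1 gene in the authors' value table, 19 without a trend in the spread and 43 among probes above background on all 16 arrays. With the lowest spot of each probe on each array, in place of the mean of its spots, 20 passed (7 higher, 13 lower), Per, Malvolio, Apid1 and GB13473-RA among them. Leaving out hive 1, 2, 3 or 4 gave 48 genes (30 higher, 18 lower), 11 (8 and 3), 18 (15 and 3) and 2 (1 and 1), so the balance of higher and lower genes depended on the hives. Without hive 2 the antioxidant list had an adjusted p of 0.106 and the ribosomal list 0.330, and without hive 4 the glutathione S-transferases were at 0.0665 and the ribosomal list at 0.106, where these lists' adjusted p ranged from 1.81e-06 to 0.493 over the alternatives.

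At day 42, apidermin 1 (Apd-1), a structural protein of the cuticle, rose by 4.03 ± 0.66 log2 (SE; 13.32 ± 0.37 against 9.29 ± 0.24, SD, n = 4 hives each), in 4 of 4 hives. The alpha-glucosidase AGLU2, which splits sucrose and related sugars, fell by 2.13 ± 0.25 (8.93 ± 0.24 against 11.07 ± 0.26) in 4 of 4 hives. The antimicrobial peptide hymenoptaecin (LOC406142) fell by 2.94 ± 0.57, catalase (Cat) by 1.56 ± 0.31 (8.0 ± 0.60 against 9.56 ± 0.23) and LOC552283, a glutathione S-transferase, by 1.21 ± 0.25. Also lower were polyubiquitin (ubq-1, LOC409675) at -1.64 ± 0.31, a secreted phospholipase A2 (LOC724436) at -1.83 ± 0.33 and at least 2.21-fold, easter (LOC726256), which in flies processes the ligand of Toll, at -1.55 ± 0.31, the growth factor Pvf1 (LOC408666) at -1.51 ± 0.30 and a tubulin (LOC408388) at -1.54 ± 0.30. A dynein (LOC725448) rose by 0.82 ± 0.16 (at least 1.17-fold). The probe for Deformed wing virus, an RNA virus of honey bees, rose by 1.82 ± 0.26 (adjusted p = 0.0189), as a mean over 4 spots that disagreed.

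In limma 48 genes passed at day 42, 10 higher and 38 lower, 22 of them named, with a median absolute change of 1.36. Their adjusted p was 0.00512 for AGLU2, 0.0310 for Apd-1, 0.0415 for hymenoptaecin (LOC406142), 0.0435 for Cat and 0.0461 for LOC552283, and 1358 genes had an unadjusted p under 0.05. Each day 42 array shared its image series with its crop's day 0 arrays. With hive as a block 66 genes passed, 44 of them among the 48, and all 12 named here kept their call. With the lowest spot of each probe 76 passed, 42 of them among the 48, and of the 12 named, 10 kept their call, while LOC552283 (0.102) and the Deformed wing virus probe (0.63, adjusted p = 0.320) lost it. The count was 61 without hive 1 (35 higher, 26 lower), 3 without hive 2 (2 and 1), 0 without hive 3 (where these 12 had adjusted p from 0.150 to 0.212) and 15 without hive 4 (8 and 7), so the excess of lower genes was not kept with any hive left out. Under 75th percentile scaling 7 genes passed (3 higher, 4 lower) and 12 in the authors' value table (1 higher, 11 lower), with the dim arrays left out 3 and with the arrays of the 2 days alone 12. Of the 12 named, these fits kept 3, 2, 1 and 5 calls, and the fit with the standard and double-sided hives added kept 4. With crop and day as additive terms and day 70 left out, 2 passed with a term for image series and 1 without it, so the drop was there before that term was added. Over all alternatives the adjusted p of AGLU2 ranged from 0.000729 to 0.150, that of Apd-1 from 0.000233 to 0.221, that of Cat from 0.00853 to 0.335 and that of hymenoptaecin from 0.00931 to 0.257.

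Among the fixed groups at day 42, antioxidant enzymes (19 of 25 lower, median -0.53, adjusted p = 9.13e-05), glutathione S-transferases (5 of 6 lower, median -0.57, adjusted p = 0.00810), antimicrobial peptides (6 of 7 lower, median -1.10, adjusted p = 0.0250), ribosomal proteins (18 of 23 lower, median -0.28, adjusted p = 0.0250) and proteasome subunits (22 of 27 lower, median -0.25, adjusted p = 0.000509) were lower. With an estimated correlation all 5 calls were lost, at an adjusted p of 0.402 for each of the first 3, 0.588 for the ribosomal proteins and 0.424 for the proteasome. By crop, the antimicrobial median was 0.85 with strawberry and -3.05 with eggplant (abaecin, LOC406144, 0.77 and -3.02, GB13473-RA 1.08 and -3.27), so the pooled value rests on eggplant. The medians with strawberry and eggplant were -0.47 and -0.37 for antioxidant enzymes, -0.94 and -0.25 for glutathione S-transferases, -0.66 and 0.0025 for ribosomal proteins and -0.14 and -0.38 for the proteasome. Members that did not pass by themselves included GstS1 at -1.63 ± 0.39, the glutathione synthesis subunit GCLM (LOC413735) at -0.88 ± 0.19 (at least 1.25-fold lower), a thioredoxin-like protein (LOC550734) at -1.0 (at least 1.75-fold lower), abaecin (LOC406144) at -1.13, RpL9 (LOC551107) at -0.69 and the proteasome subunit LOC409880 at -0.82. With hive as a block GstS1 and LOC413735 passed, at 0.0426 each, where their adjusted p without it was 0.0716 and 0.0539. Defensin Def1 was the 1 antimicrobial peptide above day 0, at 1.10 ± 0.32. Ferritin LOC551651 was at -2.35 with strawberry and 0.12 with eggplant.

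Over all genes the antimicrobial, antioxidant and glutathione S-transferase lists had 1 lower member each at day 42, which were hymenoptaecin, Cat and LOC552283. Adjusted over the list alone they had 1 higher and 3 lower, 7 lower and 3 lower, with 1 lower proteasome subunit. The direction of all 5 lists was kept under each scaling. In the additive fits without day 70 the antioxidant and glutathione S-transferase lists stayed past the threshold, and the antimicrobial list, with a mean of -0.89 in each fit, had an adjusted p of 0.213 with a term for image series and 0.170 without it. It did not pass without hive 1 (0.186) or hive 3 (0.160) either, in a range of 0.000409 to 0.822. Without hive 2 the proteasome list was at 0.0719 and the ribosomal list at 0.998, and without hive 3 the ribosomal list was at 0.160. Immune recognition and melanization genes (median 0.04, mean -0.07, adjusted p = 0.733) and immune signalling genes (median 0.08, mean -0.07, adjusted p = 0.582) did not pass. In the latter the Toll inhibitor cactus (LOC411012) was at -0.73 ± 0.17, and 2 lower members passed adjusted over the list alone.

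**Figure D1:**
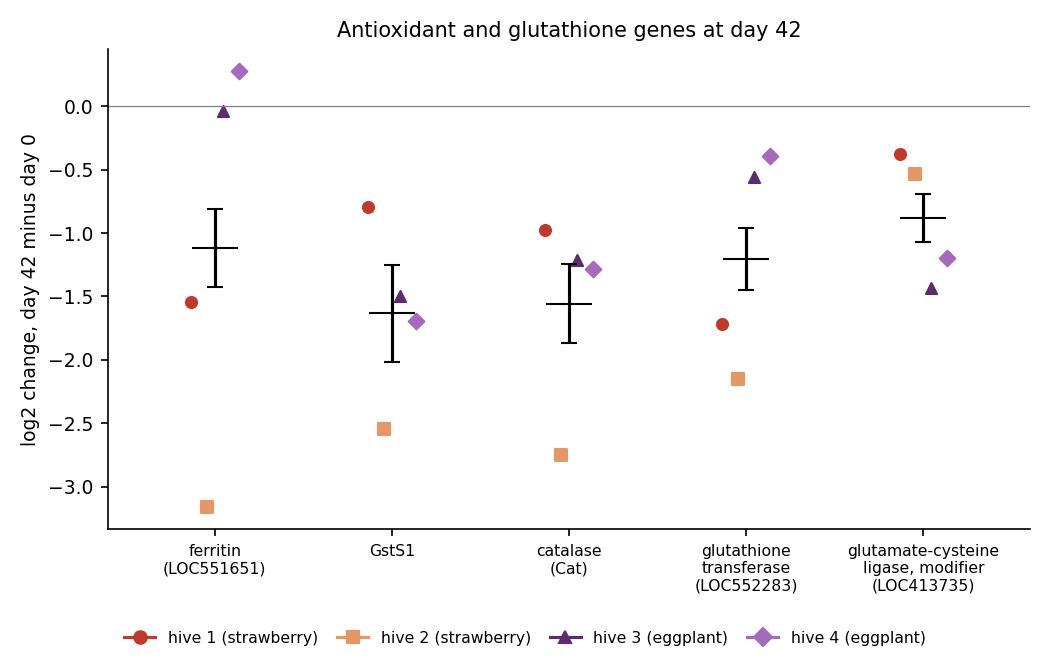
Change from day 0 to day 42 in log2 units for the ferritin LOC551651, GstS1, Cat, LOC552283 and LOC413735, with 1 point per hive and a black bar for the mean over 4 hives ± SE of the fit. Cat lay between -2.75 and -0.98 and GstS1 between -2.55 and -0.80 in the 4 hives, while ferritin LOC551651 averaged -2.35 with strawberry and 0.12 with eggplant.

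At day 70, Hemolectin (LOC411597), a clotting protein of haemocytes, fell by 2.31 ± 0.28 log2 (7.86 ± 1.44 against 10.16 ± 0.29, SD, n = 4 hives each), in 4 of 4 hives. The alpha-glucosidase Hbg2 fell by 1.41 ± 0.30, the kinase Cdk5 by 1.11 ± 0.19, the folate enzyme ALDH1L2 (LOC551401) by 1.06 ± 0.19, lamina ancestor (LOC410007) by 1.0, a trypsin (LOC408534) by 0.94, tubulin beta2 (LOC410559) by 0.92 and limb and neural patterns (LOC410702) by 0.85. Draper (LOC724466), a receptor for engulfing dead cells, rose by 1.01 ± 0.19 (8.41 ± 0.20 against 7.40 ± 0.17), and Serpin-27A (LOC726320), a protease inhibitor that restrains melanization in flies, by 1.05 ± 0.19 (at least 1.71-fold). Other rises were those of Cad87A (LOC409212) at 1.22 ± 0.26, DIP2 (LOC408342) at 1.2 ± 0.25, the kinase Wsck (LOC724127) at 1.19 ± 0.18, Dlic2 (LOC411816) at 1.11 ± 0.21, the deubiquitinase USP7 (LOC409332) at 1.09 ± 0.18, ZNF484 (LOC411780) at 1.05 and neuromusculin (LOC412893) at 1.02 ± 0.19. Ribosomal proteins were lower as a group (20 of 23 lower, median -0.41, with -0.64 in strawberry and -0.07 in eggplant, adjusted p = 0.0155, or 0.808 and no call with an estimated correlation; 0 passed adjusted over the list alone), with RpL9 (LOC551107) at -0.64 and RpL27a (LOC552318) at -0.52.

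In limma 65 genes passed at day 70, 38 higher and 27 lower, 27 of them named, with a median absolute change of 0.98, and 1677 had an unadjusted p under 0.05. Hemolectin had an adjusted p of 0.00712, draper 0.0347, Wsck, USP7 and Cdk5 0.0331 each, and Hbg2 0.04995. The fit with hive as a block passed 43 (27 higher, 16 lower), 37 of them among the 65, and Hbg2 (0.0581), Cad87A (0.0655), DIP2 (0.0568), the trypsin LOC408534 (0.0613) and tubulin beta2 (0.0502) lost their call. Every day 70 array lay in image series 3, so day and image series cannot be told apart, and these were the arrays with the lowest signal. Under 75th percentile scaling, which moved the median of all genes by 0.10 log2 at day 70, 160 genes passed (138 higher, 22 lower). With the lowest spot of each probe 3 genes passed, Hemolectin, Wsck and Cad87A, and the other named ones lost their call (draper at 0.101, Serpin-27A at 0.0610, USP7 at 0.0573) with their direction kept. Without hive 1, 2, 3 or 4 the count was 24 (17 higher, 7 lower), 4 (3 and 1), 6 (3 and 3) and 11 (8 and 3), and Hemolectin was at 0.0875 without hive 2, in a range of 0.000696 to 0.121 over its alternatives. Antimicrobial peptides (median -0.83, adjusted p = 0.162), glutathione S-transferases (-0.39, 0.162), antioxidant enzymes (-0.06, 0.634), immune recognition genes (-0.13, 0.788) and immune signalling genes (-0.04, 0.634) did not pass as groups. Adjusted over the list alone, 3 higher and 1 lower immune recognition genes passed, and over all genes 2 higher and 1 lower, which were draper, Serpin-27A and Hemolectin. Without hive 3 the ribosomal list was at 0.335.

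With strawberry, the Deformed wing virus probe rose by 3.39 ± 0.37 log2 at day 42 (11.07 ± 0.54 against 7.68 ± 0.14, SD, n = 2 hives each; adjusted p = 0.00208), to 10.69 in hive 1 and 11.45 in hive 2, within image series 1. The probe has 4 spots, which disagreed. In 1 pair of spots the signal was 12400 and 13000 in hive 1 and 26400 and 24300 in hive 2 at day 42, against 277 and 301, and 386 and 408, at day 0. In the other pair it was 312 and 346, and 412 and 321, at day 42, so the change by spot ran from 0.47 to 6.16. The change in the lowest spot of each array was 1.05 (adjusted p = 0.209). At day 42 that spot lay in the dim pair, so this value does not test the rise in the bright pair, whose spots were alike in each hive. The mean over all spots was 0.84 above day 0 at day 14 (adjusted p = 0.253) and back near the day 0 level at day 70, where hive 2 was not above background. With eggplant the change at day 42 was 0.26, and the test of the difference between crops gave an adjusted p of 0.120. Without hive 3 or 4 the strawberry value had an adjusted p of 0.0632 and 0.0625, in a range of 0.000272 to 0.342. The pooled value had 0.0758 without hive 2, 0.153 without hive 3 and 0.151 without hive 4, in a range of 0.00768 to 0.320. Of the pathogen list, whose 13 tested members include USP7 through its name, the virus probe was the 1 that passed at day 42 (list median 0.13, adjusted p = 0.208), and USP7 the 1 at day 70 (list median 0.0036, adjusted p = 0.634).

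**Figure D2:**
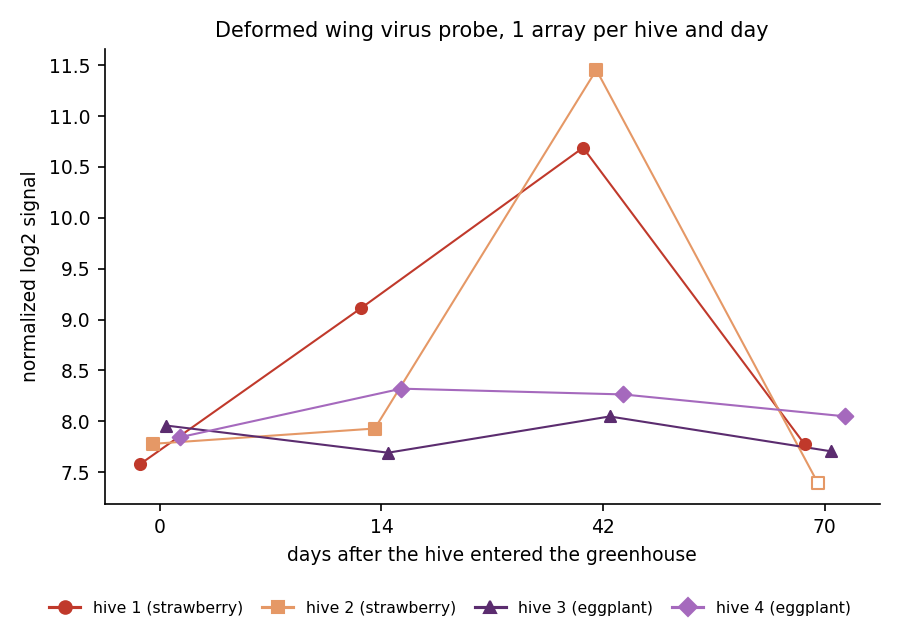
Normalized log2 signal of the Deformed wing virus probe (mean of 4 spots) by day after the move, 1 line per hive, with filled points above background and open points not. Hives 1 and 2 (strawberry) reached 10.69 and 11.45 at day 42 and hives 3 and 4 (eggplant) 8.05 and 8.26.

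With strawberry at day 14, elongation factor EF-2 (LOC409167) fell by 3.45 ± 0.59 (8.82 ± 1.21 against 12.26 ± 0.14, SD, n = 2 hives each), EF1a-F2 by 2.73 ± 0.43, ferritin LOC551651 by 2.74 ± 0.43 and the tubulin LOC408388 by 2.81 ± 0.43. N-synaptobrevin (LOC408465), a protein of synaptic vesicles, rose by 2.38 ± 0.40 and Apd-1 by 3.97 ± 0.93. FRS2 (LOC727079) and a lipase (LOC727173) were at 2.79 and 2.25 in the mean of their spots but at 0.61 and 1.29 in the lowest spot (adjusted p = 0.364 and 0.110), since they rest on single bright spots. At day 42, EF-2 (LOC409167) was lower by -3.28 ± 0.59, ferritin LOC551651 by -2.35 ± 0.43, elongation factor 1-gamma (LOC551211) by -2.26 ± 0.49 and the phospholipase A2 LOC724436 by -2.48 ± 0.47 (at least 4.01-fold). Royal jelly protein Mrjp2 rose by 3.11 ± 0.57 (12.20 ± 0.22 against 9.08 ± 0.50), n-synaptobrevin by 2.47 ± 0.40 and Apd-1 by 4.32 ± 0.93. ATE1 (LOC412018) was at 2.52 ± 0.35, from 0.68 in 1 spot and 4.35 in the other, and lost its call in the lowest spot (1.59, adjusted p = 0.0685).

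At day 70 with strawberry, Hemolectin (LOC411597) fell by 3.47 ± 0.40 (6.61 ± 0.04 against 10.08 ± 0.04, n = 2 hives each; at least 6.85-fold), lamina ancestor (LOC410007) by 1.77 ± 0.28, a tubulin (LOC550827) by 1.42 ± 0.27 and Cdk5 by 1.39 ± 0.26, of which the last 2 lost their call in the lowest spot (0.0781 and 0.0859). Gycbeta1, a guanylate cyclase subunit, rose by 2.27 ± 0.34 (at least 2.81-fold) and n-synaptobrevin (LOC408465) by 2.18 ± 0.40. In the lowest spot dpr6 (LOC725460), at 1.92 in the mean, was at -0.10 and the odorant receptor Or2a (LOC726097), at 1.71 in the mean, at 1.16 (adjusted p = 0.893 and 0.160), so neither held. As groups, ribosomal proteins were lower with strawberry at days 14, 42 and 70 (medians -0.72, -0.66 and -0.64; adjusted p = 0.00303, 0.00245 and 0.000805, or 0.612, 0.643 and 0.953, without a call, with an estimated correlation). Antioxidant enzymes (-0.47 at both days; 0.0206 and 0.00209) and glutathione S-transferases (-1.41 and -0.94; 0.00546 and 0.00291) were lower at days 14 and 42, and lost these calls with an estimated correlation (0.612 and 0.643). Adjusted over the list alone, 4 and 6 lower antioxidant enzymes passed at these days (over all genes 3 and 1), and 5 and 3 lower glutathione S-transferases (over all genes 1 and 1). Proteasome subunits were lower at day 14 (-0.37, adjusted p = 0.00478, or 0.612 and no call with an estimated correlation). Antimicrobial peptides did not pass with strawberry, with medians of -0.87 at day 14 (adjusted p = 0.246), 0.85 at day 42 (0.121) and -0.23 at day 70.

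In limma 224 genes passed with strawberry at day 14 (67 higher, 157 lower), 88 at day 42 (39 and 49) and 38 at day 70 (20 and 18). The smallest adjusted p of the named ones was 0.00187 for FRS2 (LOC727079) at day 14 and 0.00208 for the Deformed wing virus probe at day 42 (ATE1, LOC412018, followed at 0.00746), which rest on the spots given above, and 0.00336 for Hemolectin (LOC411597) at day 70. In the lowest spot of each probe 248, 106 and 17 passed, 165, 65 and 12 of them among those of the mean. Blocked by hive, the counts were 276, 108 and 38, and the tubulin LOC550827 lost its call (0.0505). Under 75th percentile scaling they were 85 (14 higher, 71 lower), 14 (8 and 6) and 7. Day 14 and day 70 lay in another image series than day 0, while day 42 did not. Without hive 1, 2, 3 or 4 the count at day 14 was 155 (73 higher, 82 lower), 47 (28 and 19), 58 (12 and 46) and 52 (10 and 42), and that at day 42 was 181 (113 and 68), 11 (8 and 3), 0 and 0, and without hive 1, 3 or 4 that at day 70 was 59, 1 and 1. With the strawberry arrays of the 2 days alone, which leave 2 arrays a side, the counts were 0, 0 and 1. Mrjp2 kept its call under 9 of 15 alternatives (adjusted p 0.00995 to 0.342).

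With eggplant, antimicrobial peptides fell at days 14 and 42, with medians of -2.47 (7 of 7 lower, adjusted p = 6.52e-13, or 0.00405 with an estimated correlation) and -3.05 (5 of 7 lower, 5.03e-07, or 0.0303). At day 70 the median was -1.43 (5 of 7 lower, 0.00641), and that call was lost with an estimated correlation (0.206). Hymenoptaecin (LOC406142) fell by 5.39 ± 0.80 at day 42 (8.18 ± 1.16 against 13.57 ± 0.24, SD, n = 2 hives each) and abaecin (LOC406144) by 3.02 ± 0.45 (7.73 ± 0.05 against 10.75 ± 0.01). At days 14 and 70, hymenoptaecin was at -3.67 ± 0.80 and -4.17 ± 0.80 without passing by itself. Adjusted over the list alone, 5, 5 and 2 lower members passed. Antioxidant enzymes (medians -0.29 and -0.37; adjusted p = 0.0122 and 0.0157) and proteasome subunits (-0.26 and -0.38; 0.0170 and 0.00132) were lower at days 14 and 42, and royal jelly proteins and hypopharyngeal gland enzymes at day 14 (14 of 16 lower, -0.42, 0.0122). These calls were lost with an estimated correlation, at 0.533 at day 14 and 0.714 at day 42. At day 70, storage proteins of the haemolymph (7 of 8 higher, 0.59, 0.00240) and DNA replication genes (23 of 34 higher, 0.19, 0.0370) were higher as groups, and both calls were lost with an estimated correlation (0.238 and 0.206). Adjusted over the list alone, 1 lower antioxidant enzyme passed at day 42 and 2 higher storage proteins at day 70.

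Gene by gene, 4 passed in limma with eggplant at day 42, all lower. They were hymenoptaecin and abaecin (adjusted p = 0.0250 each) and, named after their values were seen, LOC408807 at -3.72 and LOC726934 at -2.35. Blocked by hive, 2 passed, and hymenoptaecin was at 0.0533. There were 0 in the authors' value table and 13 under 75th percentile scaling. Without hive 2, 3 or 4 the count was 1, 0 and 15, and hymenoptaecin was at 0.0502, 0.311 and 0.0542 and abaecin at 0.0502, 0.254 and 0.129, in ranges of 0.00201 to 0.311 and 0.00201 to 0.254. At days 14 and 70, 0 genes passed in limma, with 384 and 982 at an unadjusted p under 0.05 and smallest adjusted p of 0.707 and 0.184. Blocked by hive, 0 and 1 passed, without hive 3 they were 26 and 8 and without hive 4 they were 1 and 11. Nearest to passing at day 70, besides hymenoptaecin, were sarah (LOC413142) at -1.20, Aps (LOC409489) at -1.29, Pk61C (LOC410732) at -1.53 (at least 1.98-fold lower), Wsck at 1.24 (at least 2.03-fold) and USP7 at 1.21 (at least 2.24-fold). At day 14 they were M-phase phosphoprotein LOC551711 at 1.85 (at least 2.96-fold, with spots up to 15.5-fold apart), abaecin at -2.13, Pgrp-s2 at -2.18 and GB17782-RA at -3.18 ± 0.70. The eggplant arrays of days 0, 14 and 42 shared 1 image series.

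**Figure D3:**
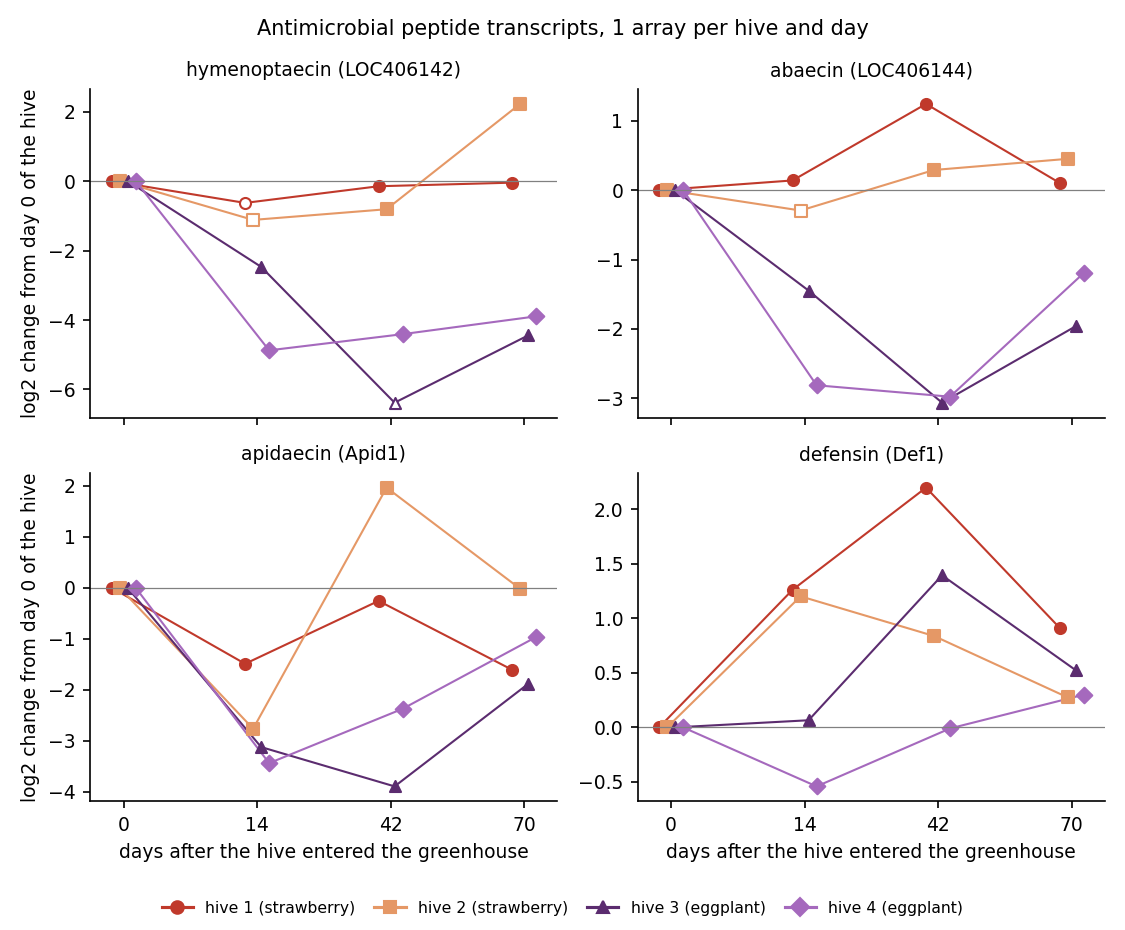
Log2 change from day 0 by day for hymenoptaecin, abaecin, Apid1 and Def1, 1 line per hive, with filled points above background and open points not. At day 42 hymenoptaecin averaged -5.39 in the eggplant hives and -0.48 in the strawberry hives, and abaecin -3.02 and 0.77.

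Before the move, the eggplant hives had more hymenoptaecin (LOC406142) than the strawberry hives, by 5.48 ± 0.80 (13.57 ± 0.24 against 8.09 ± 0.24, SD, n = 2 hives each), and more abaecin (LOC406144), by 3.08 ± 0.45. Royal jelly protein Mrjp5 was higher by 3.41 ± 0.49 (11.05 ± 0.61 against 7.63 ± 0.02) and yellow-e2 (LOC727045), of the same protein family, by 3.52 ± 0.67. The venom phospholipase Pla2 was lower at -2.46 ± 0.50, UBL3 (LOC550921) at -1.85 ± 0.37, Glucose dehydrogenase (LOC410747) at -1.75 ± 0.33 (at least 2.49-fold) and the venom protein C1q-VP at -1.70 ± 0.26. UBL3 and Glucose dehydrogenase lost their call in the lowest spot (0.148 and 0.0594). Antimicrobial peptides were higher as a group (median 1.37, adjusted p = 8.23e-05, or 0.0919 and no call with an estimated correlation), with 3 members past the threshold over all genes. In limma 160 genes differed at day 0, 125 higher and 35 lower with eggplant, with a smallest adjusted p of 2.72e-05. The crops' day 0 arrays lay in different image series, so crop and image series cannot be told apart at day 0. Without hive 1, 2, 3 or 4 the count was 63 (26 higher, 37 lower), 73 (40 and 33), 23 (22 and 1) and 34 (27 and 7), so the excess of higher genes was not kept without hive 1. Hymenoptaecin was at 0.0534 without hive 3 in a range of 0.000530 to 0.0534.

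Changes over time that differed between the crops were tested gene by gene with an F-test of the interaction in limma. FRS2 (LOC727079), at 2.79 with strawberry and -0.23 with eggplant at day 14, and dpr6 (LOC725460), at 1.92 and -0.78 at day 70, passed with an adjusted p of 0.0105 each, but each rests on single bright spots. The 2 spots of FRS2 read 8280 and 346 in hive 1 and 357 and 2600 in hive 2 at day 14, and those of dpr6 139 and 1970 in hive 1 and 1080 and 186 in hive 2 at day 70, so the bright spot was another one in each hive. With the lowest spot of each probe their adjusted p was 0.515 and 0.639 and 0 genes passed, while 23 passed among the genes whose spots lay within 2-fold on every array, so the count depends on how spots are handled. Hymenoptaecin (0.201), abaecin (0.125), ferritin LOC551651 (0.259), Mrjp2 (0.245), Hemolectin (0.305) and Apd-1 (0.698) did not pass in the main fit. With hive as a block 6 genes passed, ATE1 (LOC412018) among them at 0.0497, and FRS2 and dpr6 were at 0.0270. Without hive 1, 2, 3 or 4 the count was 56, 23, 4 and 1. All 27 lists were tested in the same way, which was chosen after the values by crop were seen. The antimicrobial peptides changed toward lower values with eggplant than with strawberry at day 14 (eggplant minus strawberry -1.47, adjusted p = 0.0365, or 0.608 with an estimated correlation) and day 42 (-3.99, 1.48e-07, or 0.0241), and at day 70 the difference was -0.61 (0.122). For hymenoptaecin and abaecin the differences in change at day 42 were -4.91 and -3.79, where the eggplant hives had started 5.48 and 3.08 higher at day 0. A fall from a higher start therefore cannot be told apart here from a change that differs by crop. In the other direction, ribosomal proteins lay higher with eggplant at day 14 (0.54, adjusted p = 0.0494) and day 70 (0.52, 0.0241), and storage proteins (1.14, 0.0422) and DNA replication genes (0.42, 0.0241) at day 70. These 4 calls were lost with an estimated correlation, at 0.916, 0.973, 0.731 and 0.188.

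The standard hive and the hive with a double-sided entrance were 1 array per day each, so their values have no replicate check. Among the genes that differed most between them, some had a higher change from day 0 in the double-sided than in the standard hive. For Mrjp7 the gap was 6.18 log2 at day 42 and 5.12 at day 70, for Mrjp4 3.54 and 3.67 and for yellow-e2 (LOC727045) 6.2 and 5.36. Yellow-e2 had 1 of 2 spots saturated in the standard hive at day 0. Its gaps are values after quantile normalization and no lower bound. The standard hive's own changes for Mrjp7 were -6.06 and -4.17, and the double-sided hive's 0.12 and 0.95. The value of 0.12 rests on the quantile normalization. Before it, the Mrjp7 spot signals in the double-sided hive were 7380 and 7470 at day 0, 2030 and 2070 at day 42 and 9570 and 9740 at day 70. In the standard hive they were 23300 and 23900 at day 0 and 154 and 160 at day 42. Mrjp5 was lower in both, at -2.91 and -2.90 in the standard and -2.33 and -1.61 in the double-sided hive. Of 16 genes in the list of royal jelly proteins and hypopharyngeal gland enzymes, 14 were below day 0 in the standard and 10 in the double-sided hive at day 42. A prostaglandin dehydrogenase (LOC551423) differed by 4.91 and 3.31 and RpS18 (LOC552726) by 4.27 and 3.12. In the double-sided hive their normalized changes at day 42 were 0.36 and 0.33. Before normalization their spot signals there fell, from 4570 and 4620 to 1550 and from 4430 and 4520 to 1480 and 1510. The size of these day 42 differences therefore rests on the scaling too. Changes were lower in the double-sided than in the standard hive for Mgat2 (LOC726476) at -3.85 and -4.10, the sodium pump subunit LOC725991 at -3.72 and -3.82 and Cad89D (LOC413210) at -3.17 and -3.25. Mgat2 and Cad89D were not above background in the standard hive at day 0, nor was LOC725991 in the double-sided hive at days 42 and 70 (at least 11.3-fold lower at day 42 than at day 0). In the standard hive the spot signals of Mgat2 before normalization were 146 and 154 at day 0 and 686 and 725 at day 42. Those of Cad89D were 151 and 172, and 445 and 458. On the normalized scale these became 20.4-fold and 6.09-fold, so the size of both rises rests on the scaling and is no lower bound. Laminin B2 (LOC409474) differed by -1.08 in 1 spot and -4.07 in the other at day 42 and the odorant receptor Or85b (LOC727389) by -1.37 and -3.67. The differences of Rock1 (LOC724539, -3.63 and -3.58) and of LOC410496 (3.52 and 3.54) come from 1 spot each, with signals of 208 and 56200 and of 260 and 33600 in the 2 spots of a day 0 array, so neither gene is taken to differ. Of 10115 genes, 426 were at least 2-fold apart in the same direction at both days (283 higher and 143 lower in the double-sided hive) and 16 in opposite directions. Spots over 2-fold apart on some array occurred in 97 of these 143 (67.8%) and 49 of these 283 (17.3%), against 16.7% of all genes, so many of the 143 rest on spots that disagree. Both days share the same day 0 arrays, which by itself gives agreement between days.

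**Figure D4:**
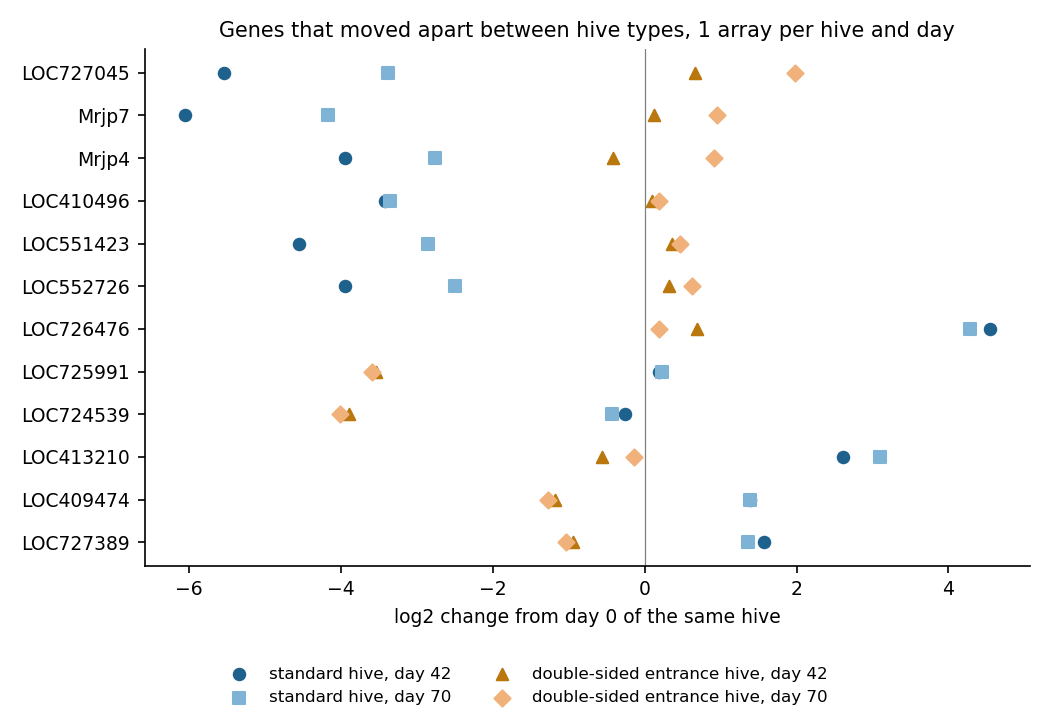
Log2 change from day 0 at days 42 and 70 in the standard and the double-sided hive for 12 genes that differed most between them, 1 array per point and no replicates. The values of Rock1 (LOC724539) and LOC410496 rest on 1 spot each. After quantile normalization Mrjp7 was at -6.06 and -4.17 in the standard hive and 0.12 and 0.95 in the double-sided hive.

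Of the genes that passed at day 42 in hives 1 to 4, 47 could be compared in these hives, and 39 (83.0%) moved the same way in the standard hive and 27 (57.4%) in the double-sided hive. Among 10000 random gene sets matched on mean expression these shares lay at percentiles 100 and 95.27. At day 70 they were 40 of 63 (63.5%, percentile 98.6) and 37 of 63 (58.7%, percentile 93.17). Catalase (Cat) was at -1.90 in the standard (not above background, at least 3.64-fold lower) and -0.96 in the double-sided hive at day 42, while Apd-1 was at 0.77 and -2.65, and the Deformed wing virus probe at 0.59 and -0.26.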

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

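The tests of single gene lists by image series, by the other hives and against housekeeping genes, and the fits with crop and day additive (with and without image series), with the dim arrays left out, with agreeing spots only and with the lowest spot, were chosen only after the result was seen. So was the condition that leaves the strawberry day 14 test undecided. The fit with 75th percentile scaling was planned before the files were seen and became an alternative once they proved to be spot quantifications. The tests of brightness, of all 3 lists jointly, of strawberry at day 14, of day 70 and of other splits were written after a first fit had shown the patterns, but before the values that decide them were computed.

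The thioredoxin-like gene LOC550734 changed by -0.55 at day 42 in hive 1 and by -1.18 to -1.12 in the other 3 hives, a gap wide against the range of the 4. The median SD of duplicate spots on the day 70 array of hive 3 was 0.103 log2, against 0.0821 to 0.083 on the other 3 arrays of that day. Of 123 such sets of 4 values, these 2 had an outlying value, where chance gives about 6.15. The changes of dpr6 (LOC725460) and FRS2 (LOC727079) differed between the crops, with an adjusted p of 0.0105 each in limma's F-test. Both rest on single bright spots, and in the lowest spot of each array the adjusted p was 0.639 and 0.515. Of 109 antisense probes, which the main comparisons leave out, 42 were above background on all 16 arrays.

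Antimicrobial, antioxidant and glutathione S-transferase lists were lower at day 42 (calls lost at an estimated correlation), and a shift that depends on brightness is argued against, since their medians lay at or below percentile 1.03 of random lists matched on mean expression. The first test of image series asked all 3 lists to be lower within each crop. It did not decide, as the highest median in eggplant was -0.25 (glutathione S-transferases, percentile 16.3), and in strawberry the antimicrobial median was 0.85. A looser test per list replaced it once these values were known and asks for 1 crop only, so its outcome was fixed and gives no support. Its values were -3.05 (antimicrobial, eggplant), -0.47 (antioxidant, strawberry, beside -0.37 in eggplant) and -0.94 (glutathione S-transferases, strawberry). By design, day 0 and day 42 of each crop share 1 series, so an offset between series does not enter these changes. A fall shared with ribosomal and proteasome genes, whose 50 members had a median of -0.28, is argued against for the antimicrobial list, at percentile 0 of random sets of those genes. That percentile counts related apidaecin entries as separate genes, so it overstates the number of independent members. The shared fall stays open for the glutathione S-transferases, at 4.07. For the antioxidant list, also at percentile 0, it stays open too. By crop, the ribosomal median with strawberry lay below the antioxidant -0.47, and the proteasome median with eggplant near the antioxidant -0.37. At day 42 the ribosomal, proteasome and antioxidant medians were -2.28, -0.96 and -0.83 in the standard hive and -1.12, -0.48 and -0.31 in the double-sided hive. In the standard and double-sided hives the antimicrobial list lay at up to percentile 79.4. Both hives stood with strawberry, where the antimicrobial median of hives 1 and 2 was 0.85 too. They therefore cannot show whether the antimicrobial fall, which rests on eggplant, was shared. The antioxidant list (0.68 or below) goes with a change shared by these hives, and the glutathione S-transferases (27.2 or below) leave it open. Season, bee age and crop, which go with day and hive here, stay open and were not tested.

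The 224 genes that differed with strawberry at day 14 were read on other image series than day 0, so a series difference is a candidate explanation. By the bound written first, the comparison of eggplant and strawberry at day 42, which spans the same 2 series, would argue against it, with a signed median of -0.18 (interval -0.22 to -0.10) of that at day 14. That comparison subtracts strawberry day 42 arrays, in which these genes already stood at 1.15 inside the day 0 series, which lowers the value with or without a series effect, so it does not decide. Their signed median was 1.62 at day 14 and 0.08 with eggplant at day 14, where 127 (56.7%) moved the same way, and days 14 and 42 share the strawberry day 0 arrays, from which part of the likeness may come. A series difference and a change in these 2 hives over time both stay open.

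The 65 genes of day 70 were all read on image series 3, with the lowest signal, and group and series cannot be told apart. The standard and double-sided hives, whose arrays lie outside these series, moved the same way for 63.5% and 58.7% of 63 genes at day 70. The shares lay at percentiles 98.6 and 93.2 of random sets, and the test asked both hives to lie in the top 2.5%, so it does not decide between a series difference and a change over time. Under 75th percentile scaling 160 genes passed, 138 of them higher, among probes above background on all 16 arrays 0 passed, and with the lowest spot of each probe 3. With the standard and double-sided hives added 0 passed and 0 of 17 named calls were kept, while among genes with agreeing spots the count rose.

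Other splits of the 8 arrays of each comparison into 4 and 4 were fitted as 2 groups without crop, which gave the real split of day 42 only 2 genes where the fit by crop and day gave 48, so they do not test the latter. For genes at days 14 and 70 and lists at day 70 the real split gave 0, all 35 splits match that by construction, and nothing follows from them (highest others 116, 466 and 6). For genes at day 42, 2 of 35 splits, the real one included, gave at least its count, and the only other one, with 81, was the split by crop. For the lists, 9 of 35, the real one included, gave at least its count at day 14 (real 6, highest other 8) and 9 at day 42 (real 3, highest other 6). In this fit without crop, chance is therefore not excluded for these 3 counts. For genes at day 42 that rests on the split by crop alone. The split by crop gave 116, 81 and 466 genes in the arrays of days 14, 42 and 70, each with day 0. The crops' day 0 arrays lie in different image series, and at day 42 the split by crop is also that between series 1 and 2, so crop and image series cannot be told apart in these counts. Among the 8 splits that part the 2 arrays of every hive, the highest other gave 8 lists at day 14 and 0 genes and 2 lists at day 42.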

How the results depend on the processing

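The fits with crop and day additive (with and without image series), with the dim arrays left out, with agreeing spots only and with the lowest spot of each probe were chosen after seeing the data. The others were planned, 75th percentile scaling first as the main setting. For named genes, 2455 alternative values kept direction and side of the threshold, 405 kept direction and lost the call, 71 gained one and 16 changed direction. For the lists of the study's theme and the ribosomal and proteasome lists the counts were 364, 32, 5 and 12, and of the counts of genes and lists 148 lay within 1.5 times the main one and 104 did not. The 2455 and 364 include genes and lists that did not pass in the main fit and stayed so. They therefore do not give the share of calls kept. Of the 12 named calls at day 42, 12 were kept with hive as a block, 10 with the lowest spot and 3 under 75th percentile scaling. Of the 17 at day 70, these fits kept 12, 3 and 15. The 20 other values, on the standard and double-sided hives, all lay within wide limits. For shares of genes moving the same way the limit was the binomial confidence interval of the main share. For the double-sided hive at day 42 it ran from 42.2% to 71.7%. For the hive type count it was 1.5 times, and quantile scaling without background correction gave 288 against 426. Unless stated, the cause was not tested.

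With hive as a replicate block, 27 genes passed at day 14 (from 0), 43 at day 70 (from 65), 2 with eggplant at day 42 (from 4), 1 with eggplant at day 70 (from 0) and 6 in the test of change between crops (from 2). Beyond the calls given in the report, the block changed no other call of a named gene or list. It gives no value for the crops at day 0, since hives lie within crops. Hive as a random block and quantile scaling without background correction moved no count by over 1.5 times. Slide as a block was not run, since each slide held 1 array.

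Under 75th percentile scaling, the scaling named in the plan before the files turned out to be spot quantifications, 7 genes passed at day 42 (from 48), 160 at day 70, 85, 14 and 7 with strawberry at days 14, 42 and 70 (from 224, 88 and 38), 13 with eggplant at day 42, 0 in the test of change between crops and 2 lists at day 70 (from 1). That scaling moved the median of all genes by 0.10 at day 70 and 0.12 with eggplant at day 70. In the authors' value table the counts were 1 gene at day 14, 12 at day 42, 26 at day 70, 54 and 15 with strawberry at days 42 and 70, 0 with eggplant at day 42 and 5 in the test of change between crops. Without a filter on dim probes, which adds genes to adjust over, 18 passed at day 42. Among probes above background on all 16 arrays, which leaves fewer genes, 43 passed at day 14, 0 at day 70, 101 with strawberry at day 70, 100 between crops at day 0 (from 160), 7 in the test of change, 3 lists at day 42 (from 5) and 0 lists at day 70. Without a trend 19 genes passed at day 14 and 4 in the test of change. With all probes tested 42 passed at day 70, with 2 lists. At 2-fold or more 29 passed at day 70.

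With the arrays of the compared groups alone, which leaves fewer arrays for the spread, 12 genes passed at day 42, 113 at day 70, 0, 0 and 1 with strawberry, 1 with eggplant at day 70 and 87 between crops at day 0. With an estimated correlation 0 lists passed at days 14, 42 and 70 (from 6, 5 and 1). With the dim arrays left out 3 genes passed at day 42. With crop and day additive and day 70 left out, 2 passed at day 42 with a term for image series and 1 without it, so the move from 48 does not come from that term. Only 5331 of 9959 genes had spots within 2-fold of each other on every array, and with these, which leaves out the noisier genes, 71 passed at day 14, 175 at day 42, 227 at day 70, 174 and 184 with strawberry at days 42 and 70, 17 and 7 with eggplant at days 42 and 70, 23 in the test of change, 3 lists at day 42 and 0 at day 70. With the lowest spot of each probe on each array, which takes the weight from single bright spots, 20 passed at day 14, 76 at day 42, 3 at day 70, 17 with strawberry at day 70 and 0 in the test of change. With the standard and double-sided hives added and hive as a replicate block, 369 genes passed at day 42 (38 higher, 331 lower), 0 at day 70 and 5 lists at day 70.

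Leaving out 1 hive at a time gave 2 to 48 genes at day 14, 0 to 61 at day 42 and 4 to 24 at day 70. With strawberry it gave 47 to 155, 0 to 181 and 1 to 59 at days 14, 42 and 70, and with eggplant 0 to 26, 0 to 15 and 0 to 11. Between crops it gave 23 to 73 at day 0 and 1 to 56 in the test of change, and lists ranged from 3 to 10 at day 14, 3 to 6 at day 42 and 0 to 1 at day 70. A hive left out leaves its crop with 1 array a day, which is assumed to vary like the other groups.

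Of the values that changed direction, 2 were past the threshold in the main fit. Limb and neural patterns (LOC410702) at day 70 (-0.85) was at 0.044 with the added hives, and dpr6 (LOC725460) with strawberry at day 70 (1.92) was at -0.10 in the lowest spot. The mean of the immune signalling list at day 14 was 0.0051 without background correction, 0.013 without a filter, 0.038 in the lowest spot, 0.090 among probes above background on all 16 arrays and -0.036 to 0.034 with 1 hive left out, and at day 70 it was 0.010 under 75th percentile scaling. The immune recognition mean was 0.022 at day 42 and 0.072 at day 70 among probes above background on all 16 arrays, 0.050 at day 42 with all probes and 0.010 at day 70 in the lowest spot. The antioxidant mean at day 70 was 0.0019 in the lowest spot. At day 14, LOC409246 was at -0.069 and LOC413271 at -0.035 in the additive fit with image series, and at 0.57 and 0.33 in that without it. The Deformed wing virus probe at day 70, at -0.06, was at 0.043 under 75th percentile scaling (strawberry 0.0081, eggplant 0.078) and 0.13 with the added hives. With 1 hive left out it ranged from -0.20 to 0.087 (strawberry -0.39 to 0.20, eggplant -0.25 to 0.21), and with eggplant at day 14 from -0.27 to 0.48. In the lowest spot it was at -0.069 at day 14 (strawberry -0.070, eggplant -0.068).

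Signal over background limits which genes can be tested, with 55.1% to 83.4% of probes above it and the lowest share on the day 14 array of hive 4. The median signal was lowest at day 70, at 143.2 to 202.5, but the share above background was not. In simulated data a pooled contrast recovered 61.5% of 2-fold changes and a contrast within strawberry 13.5%, so calls within 1 crop miss most changes of that size.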

Other observations

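The comparison of changes that share day 0 arrays and the gene list medians of the 2 other hives were chosen only after the result was seen.

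Members of the list of royal jelly proteins and hypopharyngeal gland enzymes lay on both sides of day 0 at day 42. The list takes alpha-glucosidases by name, and in whole-body RNA the tissue that made these transcripts was not measured. The alpha-glucosidases AGLU2, at -2.13 ± 0.25, and Hbg2, at -1.45, fell (adjusted p = 0.00512 and 0.0495 in limma), and Hbg3 was at -2.32 without passing. Royal jelly proteins Mrjp2, at 1.80, Mrjp7, at 1.70, and Mrjp3, at 1.11, lay above day 0 without passing. Of the list's 16 members, 11 were higher and 5 lower (median 0.37, mean 0.06, adjusted p = 0.915), with 2 lower over all genes, and 3 higher and 4 lower adjusted over the list alone. Hbg2 and Mrjp2 at day 42, Hbg3, Mrjp3 and Mrjp7 were chosen after their values were seen.

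In the standard hive, 1 array a day, the medians of several gene groups were lower at day 42 than at day 0. The 8 lowest were -2.28 for ribosomal proteins, -2.13 for the royal jelly group, -1.22 for glutathione S-transferases, -1.20 for oxidative phosphorylation, -0.96 for the proteasome, -0.94 for glycolysis and trehalose genes, -0.88 for heat shock proteins and chaperones and -0.83 for antioxidant enzymes. In the double-sided hive the same medians were -1.12, -0.10, -0.30, -0.32, -0.48, -0.42, -0.74 and -0.31. Storage proteins of the haemolymph were at -0.35 in the standard and 0.35 in the double-sided hive. These values have no replicate check.

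Of the pathogen probes, 24 besides Deformed wing virus were tested, with log2 changes between -0.70 and 0.68 and a smallest adjusted p of 0.185.

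Changes at days 14 and 42 against day 0 correlated at r = 0.676 across genes, days 14 and 70 at 0.493 and days 42 and 70 at 0.474, where simulated unchanged groups against the same day 0 arrays gave 0.499, 0.502 and 0.503. With the day 0 arrays split between the 2 comparisons, r was 0.377 and 0.404, 0.239 and 0.238, and 0.240 and 0.216. The covariances were 0.0852, 0.0621 and 0.0613 against 0.0331, 0.0334 and 0.0335 simulated, differences of 0.0521, 0.0287 and 0.0278. Genes are not independent replicates.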
